A study of Rattus norvegicus with 6 samples.

How the data were processed

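Kidney RNA of 6 male Wistar rat samples was analysed as 1 deposited expression table, with 3 control and 3 FSGS libraries. FSGS stands for focal segmental glomerulosclerosis, a disease in which parts of the kidney's filtering units scar. Per the labels' protocols, the model animals lost the left kidney by surgery and received adriamycin, an anthracycline drug that damages DNA and is toxic to glomerular cells, by tail vein. The doses were 5 mg/kg on day 7 and 3 mg/kg on day 28 after surgery. Controls received saline, and no surgery is stated for them, so the effects of nephrectomy and of the drug cannot be told apart in this design. The sample titles call every sample untreated, while the treatment field gives the injections; groups were taken from the group name in the titles. The labels do not say in so many words that each library is a separate animal, so p-values measure the spread between these samples, which may be partly technical.

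Per the labels' protocols, RNA was enriched for poly(A) transcripts with oligo(dT) beads, strand-marked with dUTP and sequenced as paired ends on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without a role for any of them. The genome build and annotation were not given in the sources used here. The deposited values are FPKM per the file headers, that is, fragments mapped to a gene, scaled by the authors for gene length and for the total of mapped fragments. They were checked to carry at most 2 decimals. All 6 sample columns were used, and each was matched to its sample by the short name in the description field.

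FPKM values carry no counts, so depth is unknown and no counting interval or detection limit is given. Low values were tested for steps that whole reads would leave: in genes listed at 0 in at least 2 libraries, the log2 ratio of values of at least 0.3 between library pairs put at most 12.5% of genes in any window of 0.05, over pairs with 16 to 136 genes. No steps were seen, and no reads were recovered. An FPKM is a share of each library, so a rise in a few very abundant transcripts lowers all others. A share of summed FPKM is weighted by gene length and is not a share of reads.

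Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, 14139 of 21986. The values were transformed as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted group alone with a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. All changes are FSGS minus control. Single measures were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.

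Gene sets were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Camera compares a set with the other genes, while fry tests the set against no change. The procedure was tested on simulated data with 13772 genes passing the filter and 200 changed. It called 82% of the genes changed by 1 on the log2 scale and 95% of those changed by 2. There were 16 false calls, and 0 changed genes had an estimate of the wrong sign. The changed genes were drawn above a floor of control abundance, errors were independent between genes, and no shift of a column was simulated. The figures therefore do not cover the lowest genes tested, correlated genes, column scaling or a change in as many genes as were called here.

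The table identifies genes by Ensembl ID and chromosome and does not pair the IDs with names. The RefSeq gene table used here for names (assembly GRCr8) carried an Ensembl ID in 0 of its 47357 rows, so 0 IDs were matched. The peroxiredoxin genes named in the series title, the gene lists and the cell type markers fixed before the data were examined were therefore not analysed here. The parts of the rule for named genes that need a symbol were not applied. What remained of that rule took the 10 largest increases and decreases with adjusted p under 0.05, no overlap between groups and a mean FPKM of at least 5 in the higher group. From these, the leading 2 in each direction are named by ID, without coordinates, since no build was given.

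The per-gene test, its thresholds, the rule for named genes and the alternative settings were chosen before the data were examined. These descriptions were chosen after seeing the data, to replace the lists: fold-change classes, chromosome sets (23, with the mitochondrial genome among them), abundance classes and the division of mitochondrial genes at 2000 FPKM, the most abundant genes, genes listed at 0 in a whole group, the distance of the mitochondrial median from that of all genes, and the comparison of single replicates. The alternatives were other pseudocounts, filters, scalings and limma options, a fold-change threshold, the replicate number as a block, and each library left out in turn. Median-of-ratios and quantile scaling, rescaling to TPM, and rescaling without the 50 most abundant and the mitochondrial genes were the scalings tried.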

Results

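RNA levels were compared between 3 control kidney samples and 3 kidney samples from the FSGS rat model, made by removal of 1 kidney and 2 adriamycin injections. The series addresses PRDX proteins in this disease; those genes were not analysed here, because the table does not pair IDs with names. The summed FPKM was 614047, 643034 and 691777 in controls 1, 2 and 3, and 754892, 796899 and 824403 in FSGS 1, 2 and 3. The column totals thus did not overlap between the groups. Genes at 1 FPKM or more numbered 12311, 12405 and 11884 in controls 1, 2 and 3, and 12718, 12768 and 12439 in FSGS 1, 2 and 3. The group means were 12200 ± 278 and 12642 ± 177 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest this design allows).

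FSGS and control kidneys differed in 6222 of the 14139 genes tested, of which 3814 rose (27.0%) and 2408 fell (17.0%). Among them, 1220 rose and 1012 fell by at least 2-fold, 252 rose and 266 fell by at least 4-fold, and 63 rose and 73 fell by at least 8-fold. The 3 FSGS values lay all above or all below the 3 control values in 7865 genes (55.6%), where chance gives 10%. The libraries separated by group along the first principal component, which held 80.3% of the variance, with controls at -53.8, -43.3 and -52.2 and FSGS libraries at 42.4, 51.6 and 55.3. On the second component (7.65%), replicate 3 of each group lay apart from the others, at -20.2 in controls and -21.8 in FSGS. Pearson correlations of log2 values across genes were 0.977 to 0.986 within groups and 0.848 to 0.903 between them; genes are not independent replicates.

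The balance of rising and falling genes depended on the scaling of the columns. It was 3463 against 3485 with median-of-ratios scaling, 3620 against 3386 with quantile normalization, 2012 against 3191 after rescaling to TPM, and 5644 against 2284 after rescaling without the most abundant and mitochondrial genes. The median log2 change of all genes was 0.11 as deposited, and 0.007, 0.006, -0.12 and 0.22 in the same order. Changes below are as deposited and should be read against the median of 0.11.

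**Figure D1:**
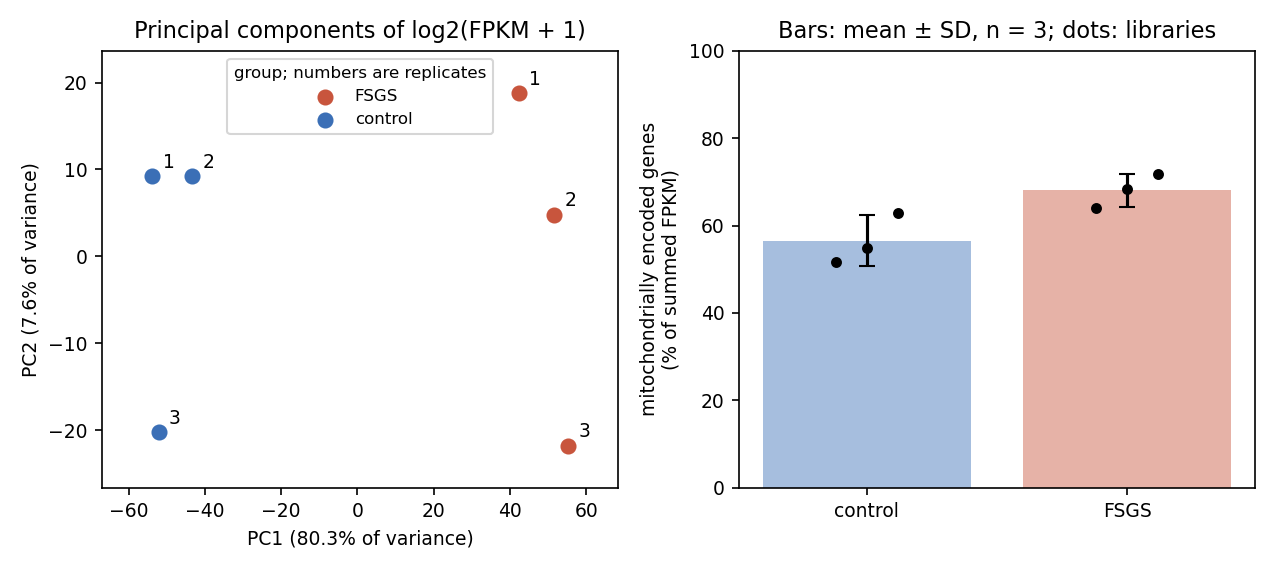
Left, the 6 libraries on the first 2 principal components of log2(FPKM + 1), with replicate numbers; the first component (80.3% of variance) separates the groups. Right, mitochondrially encoded genes as a percentage of summed FPKM, with bars for the mean, error bars for the SD (n = 3) and dots for libraries, from 51.6% to 62.9% in controls and 64.0% to 71.7% in FSGS.

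Mitochondrially encoded transcripts, which code for respiratory chain subunits and for the RNAs of mitochondrial translation, took a larger share of the FSGS libraries. They made up 51.6%, 55.0% and 62.9% of summed FPKM in controls 1, 2 and 3, and 64.0%, 68.4% and 71.7% in FSGS 1, 2 and 3. The means were 56.5% ± 5.84 and 68.0% ± 3.86 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). Of the 37 mitochondrial genes, 17 rose, 1 fell and 33 had a log2 change above 0, with a range of -0.83 to 2.16 and a median of 0.53. Of the 14 with a mean of 2000 FPKM or more, 3 rose and 1 fell; of the 23 below it, 14 rose and 0 fell by limma at adjusted p under 0.05. The increases under every scaling tried came from 9 genes, all below 2000 FPKM, with log2 changes of 1.02 to 2.16 as deposited. Without names, it is not known here whether these 9 code for respiratory chain subunits or for the RNAs of mitochondrial translation. The libraries were enriched for poly(A) transcripts, which may affect these kinds of RNA unequally.

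As a set, the mitochondrial genes were the only 1 of 23 chromosome sets to pass camera's test (adjusted p = 0.00549), and the call did not hold in several settings. The correlation estimated for this set was 0.48, far above the preset 0.01, and with it camera's adjusted p was 0.993 (unadjusted camera p = 0.372). At the preset correlation camera's adjusted p was 0.0846 with median-of-ratios scaling and 0.404 after rescaling without the most abundant and mitochondrial genes. It was 0.0898 without FSGS replicate 3. With fry, which tests against no change and so asks another question, the adjusted p was 0.109. The set's median log2 change lay 0.42 above that of all genes as deposited and 0.52 above it with quantile normalization. With median-of-ratios scaling, TPM and the rescaling without the most abundant and mitochondrial genes the gap was 0.39, 0.36 and 0.45. It was thus of similar size in the scalings where the set call was lost. These scalings use 1 factor per column, which shifts all genes nearly alike and so cannot test this gap. Taken per library as deposited and relative to the control means, the gap was -0.24, -0.07 and 0.29 in controls 1, 2 and 3. It was 0.16, 0.54 and 0.71 in FSGS 1, 2 and 3, so the groups overlapped (two-sided exact permutation p = 0.2). They overlapped under the scalings by 1 factor per column too (exact p = 0.2 each), and not with quantile normalization (exact p = 0.1). That normalization sets 1 distribution for every column, which may by itself have changed the spread. The SD of the control gaps was 0.09 with it and 0.27 as deposited. The number that rose was 9 with median-of-ratios scaling, and 11 without control replicate 1, FSGS replicate 2 or FSGS replicate 3.

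**Figure D2:**
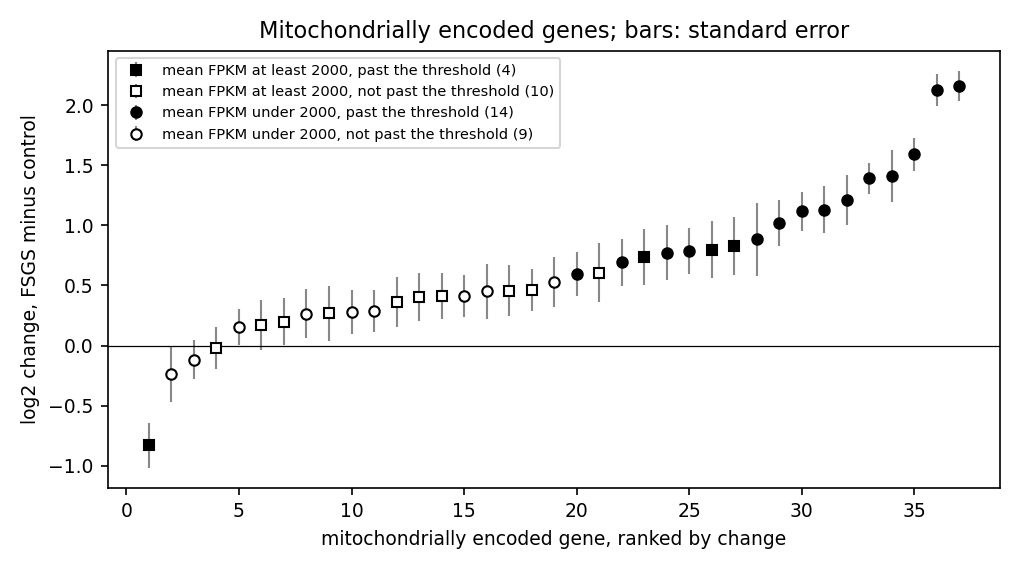
Log2 change (FSGS minus control) of the 37 mitochondrially encoded genes, ranked by change; symbols are the limma estimates, bars are standard errors, squares are genes of at least 2000 FPKM, circles are the rest, and filled symbols passed the threshold. The changes run from -0.83 to 2.16, and 17 genes rose as deposited, 9 of them with median-of-ratios scaling.

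Among nuclear genes, the most abundant fell more often than they rose. Of 427 nuclear genes with a mean of 100 FPKM or more, 93 rose and 200 fell, with a median log2 change of -0.36. The scalings by 1 factor per column gave more falling than rising genes too, with 80 against 226 for median-of-ratios, 46 against 220 for TPM and 122 against 191 for the rescaling without the most abundant genes. Quantile normalization gave 165 against 169, but it sets 1 distribution for every column and so tends to balance such a class by construction. Of 4383 nuclear genes between 10 and 100 FPKM, 1117 rose and 1021 fell as deposited, and this balance turned with the scaling. It was 1019 against 1516 with median-of-ratios, 479 against 1308 with TPM, and 1796 against 983 with the rescaling without the most abundant genes. Between 1 and 10 FPKM 2232 rose and 1031 fell, and between 0.5 and 1 FPKM 355 rose and 155 fell. The classes below 10 FPKM moved with the scaling too: over 0.5 to 10 FPKM, 2587 rose and 1186 fell as deposited, and 1475 rose and 1662 fell after rescaling to TPM.

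The most abundant nuclear transcripts differed in part between the groups. Of the 20 most abundant nuclear genes in controls, 16 fell and 1 rose, and of the 20 most abundant in FSGS, 11 rose and 3 fell; 7 genes were in both lists. Each list was picked in 1 group, which by itself favours these directions. The most abundant nuclear gene of the controls, on chromosome 4, fell from 6078 ± 822 to 268 ± 313 FPKM (SD, n = 3; log2 change -5.16 ± 0.66 SE, limma adjusted p = 0.000444) and ranked 94 in FSGS. Its FSGS values were 629, 96.1 and 78.1 FPKM in replicates 1, 2 and 3. The most abundant nuclear gene of FSGS, on chromosome 14, rose from 420 ± 255 to 8242 ± 1305 FPKM (log2 change 4.46 ± 0.38 SE, limma adjusted p = 6.84e-05), from rank 64 in controls.

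**Figure D3:**
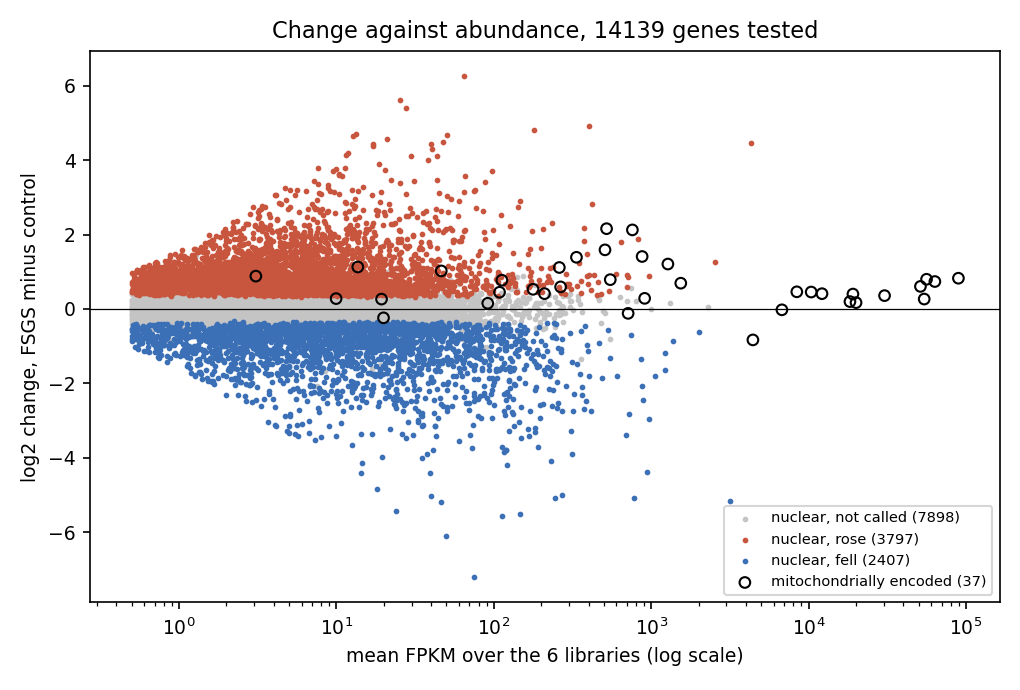
Log2 change (FSGS minus control) against mean FPKM over 6 libraries (log axis) for the 14139 genes tested; red nuclear genes rose, blue fell, grey did not pass, and open circles are the 37 mitochondrially encoded genes. Of nuclear genes at 100 FPKM or more, 93 rose and 200 fell as deposited; quantile normalization, which tends to balance such a class by construction, gave 165 and 169.

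By the rule for named genes, 2394 increases and 1740 decreases qualified, and the 10 largest increases had log2 changes of 4.48 to 6.27. Of the 10 largest decreases, 9 had an FSGS mean above 0 and log2 changes of -6.10 to -5.04. ENSRNOG00000007243 on chromosome 10 rose from 0.513 ± 0.475 to 129 ± 78.9 FPKM (SD, n = 3; log2 change 6.27 ± 0.42 SE, limma adjusted p = 2.54e-05). ENSRNOG00000025571 on chromosome 13 was listed at 0.1, 0 and 0 FPKM in controls 1, 2 and 3 and rose to 57.3, 39.2 and 54.9 FPKM in FSGS 1, 2 and 3 (limma adjusted p = 8.53e-07). ENSRNOG00000057928 on chromosome 1 fell from 175, 137 and 135 FPKM in controls 1, 2 and 3 and was listed at 0 in all 3 FSGS libraries (limma adjusted p = 5.54e-08). ENSRNOG00000039350 on chromosome 10 fell from 98.8 ± 4.85 to 0.49 ± 0.40 FPKM (log2 change -6.10 ± 0.18 SE, limma adjusted p = 8.53e-07).

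Genes listed at 0 in all 3 libraries of 1 group, above 0 in all 3 of the other and averaging at least 1 FPKM there numbered 12 for controls at 0 and 17 for FSGS at 0. In their higher group the 12 averaged 1.06 to 4.64 FPKM and the 17 averaged 1.05 to 149 FPKM. An exact 0 in FPKM can be a failed estimate.

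Across nuclear chromosomes, chromosome 20 had 161 of 446 genes rising (36.1%) and 74 falling. It was looked at for this share, and its set test did not pass (camera adjusted p = 0.966, 0.993 with an estimated correlation, 0.43 with fry).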

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

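The fold-class, mitochondrial and abundance counts and the mitochondrial set test were chosen after seeing the data, while the alternatives were planned. Those for peroxiredoxins and gene lists were not run, for lack of names. The 4 named genes kept their direction and call under all 19 alternatives, with limma adjusted p between 1.26e-11 and 0.000616. This follows largely from their selection in the same data and does not speak for other calls. Their sizes moved with the pseudocount: ENSRNOG00000007243 from 4.42 (pseudocount 5) to 7.78 (0.1) on the log2 scale, ENSRNOG00000025571 from 3.44 to 8.63 and ENSRNOG00000039350 from -4.24 to -7.59; ENSRNOG00000057928, listed at 0 in FSGS, has no fold. No gene called both as deposited and under an alternative changed sign. Called genes ranged from 2232 to 7928. At mean FPKM of at least 5, 3672 genes were called, 2068 rising and 1604 falling, with 674 rising at least 2-fold; fewer genes were tested. With a log2 change of at least 1 required, 2232 were called, 1220 rising and 1012 falling, with 9 mitochondrial genes rising and 29 rising at 100 FPKM or more, by construction. Rises of at least 2-fold numbered 1949 with pseudocount 0.1 and 466 with pseudocount 5, and falls 565 with pseudocount 5, since the pseudocount sets fold sizes of low genes. After rescaling to TPM 2012 genes rose, 1601 fell at least 2-fold, and 46 rose at 100 FPKM or more; with quantile normalization, which tends to balance abundant genes, 165 did. Mitochondrial rises numbered 9 with median-of-ratios scaling, 10 with no filter, and 11 to 17 leaving out single libraries (11 without control 1, FSGS 2 or FSGS 3). The mitochondrial set test gave adjusted p = 0.0846 with median-of-ratios scaling, 0.404 rescaled without the most abundant and mitochondrial genes, 0.993 with an estimated correlation and 0.109 with fry, and 4.31e-05 to 0.0898 leaving out single libraries, highest without FSGS 3. Where no reason is given, the cause was not tested. With the replicate number as a block 6900 genes were called. Deviations of same-numbered libraries correlated at 0.13, 0.03 and 0.02. Controls 1 and 3 matched their own number best, and control 2 matched FSGS 3 (0.09). Numbers were not taken as pairs, but replicate 3 of both groups lay low on the second component, so a shared replicate effect stays open. Depth, and so its limit on low genes, is unknown.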

Other observations

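Of the tests here, those of column scaling for the mitochondrial genes, of slopes by direction and of a weaker response in FSGS 1 were chosen after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 6222 genes and the highest of the others 0 by limma. At an unadjusted p under 0.05 by limma the others had 79 to 311 genes and the real split 7322. Each other split put libraries of both groups on both sides, which widened the spread within sides. Low counts were thus built into those splits, and they are no baseline for chance. Only the real split (1 of 10) reached its own count, and 10 splits are too few for a share under 0.05.

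Mitochondrially encoded genes rose in FSGS in 17 of 37 cases. A common rise of all mitochondrial RNA was tested by dividing each library by its mitochondrial total. In a limma fit of these genes alone, 20 of 37 (54.05%) then passed the threshold, 10 up and 10 down relative to that total. P-values were adjusted over the 37 genes here, not over all genes tested. The genes moved apart from each other, which argues against 1 shared factor as the whole of the rise. With median-of-ratios scaling 9 of the 17 still rose, barely over the bound set after the values were seen. The set's median log2 change was 0.39 with that scaling, against 0.53 as deposited. Column scaling stays open for the calls that were lost. They were lost when the scaling alone was changed, which does not show whether their rise as deposited came from the scaling. The set's excess over the median of all genes, which a factor per column hardly moves, overlapped between the groups as deposited. It was 0.29 in control 3 and 0.16 in FSGS 1 (two-sided exact permutation p = 0.2). With quantile normalization it did not overlap, at most 0.096 in controls and at least 0.23 in FSGS (exact p = 0.1, the smallest possible). Since that normalization sets 1 distribution for every column, it may by itself have changed this spread. A biological change with the model also stays open, as the surgery and drug were given only to the FSGS group.

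FSGS replicate 1 lay nearest the controls on the first principal component. Its slope on the other FSGS libraries over the 6222 called genes was 0.873, against 1.01 and 1.05 for FSGS 2 and 3. Control RNA mixed into the library would leave 1 common share of the control level in genes almost lost from FSGS 2 and 3, but over 30 such genes the share ran from 0.664% at the 10th percentile to 14.9% at the 90th, which argues against mixing as the whole cause. Rescaling without the most abundant and mitochondrial genes left the slope at 0.867, under the bound of 0.95 set beforehand. A slope over both directions hardly responds to such a shift, while the slopes by direction do. After the rescaling these were 0.769 ± 0.009 over falling and 0.938 ± 0.007 over rising genes (jackknife SE over 23 chromosomes). The errors measure the spread between genes of 1 library, not between samples. The rescaling thus did not bring this library's slopes to 1. Whether they differ from 1 by more than libraries usually do cannot be told from 1 library, so the share of mitochondrial RNA stays open as a cause. A weaker response of FSGS 1 may explain its place nearest the controls and cannot be told apart from a response that differs by direction. Its slope over falling genes was 0.728, 0.798 and 0.769 as deposited, with median-of-ratios scaling and with that rescaling. Over rising genes it was 1.03, 0.942 and 0.938 in the same order. FSGS 1 was not the only library away from 1. Over falling genes the slope of FSGS 3 was 1.26, 1.17 and 1.19, and that of FSGS 2 was 1.00, 1.01 and 1.00. Over rising genes they were 0.899, 0.998 and 1.00 for FSGS 3 and 1.02, 0.991 and 1.01 for FSGS 2. Each slope was taken on the other 2 FSGS libraries. A weak fall in FSGS 1 therefore cannot be told apart from a strong fall in FSGS 3.

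Control 2 was the highest control in 57.6% of the genes that rose and in 43.0% of all genes tested as deposited, in 49.2% and 35.6% with median-of-ratios scaling, and in 44.5% and 32.8% with quantile normalization.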
